A study of Saccharomyces cerevisiae with 5 samples.

How the data were processed

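Nucleosomes of budding yeast arrested in G1 were measured on 5 two-colour Agilent tiling arrays, 1 array for each nucleosome fraction, so no comparison between fractions has a replicate and no test or p-value is given. The strain carries a FLAG-tagged copy of HTZ1, the gene of the histone variant H2A.Z, in the BY4741 background. Per the strain label it also has a bar1 deletion. Per the labels, the cells were held with alpha factor at 1 mg/L for 90 min, crosslinked in 3% paraformaldehyde for 15 min, and their chromatin was cut with micrococcal nuclease (MNase). The 5 fractions are total nucleosomes, all nucleosomes bound by the anti-FLAG antibody (called H2A.Z total here), and the types with 2 copies of H2A (AA), 1 of each histone (AZ) and 2 copies of H2A.Z (ZZ). Per the labels' protocols, AA was taken with an anti-H2A antibody from what the anti-FLAG beads left, and AZ with an anti-H2A antibody from the FLAG eluate. The labels do not state how the ZZ fraction was recovered after that step, so what the ZZ values hold rests on the name of the fraction alone. On every array the fraction was labelled with Alexa 555 (green) and MNase-treated genomic DNA with Alexa 647 (red), with no dye swap, and both were amplified by ligation-mediated PCR.

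Per the file headers, the deposited scanner values are intensity values of each spot from Feature Extraction 10.1.1.1: the processed signals are background-subtracted, detrended and brought to 1 scale per dye by a linear factor, without lowess. The mean and local background signals in the same files are intensity values with no correction, per the file headers. The deposited LogRatio is the log10 of red over green per the file headers, and served only to check the direction. The other columns used are 0 or 1 flags of the extraction software, per the file headers. The authors' deposited value table holds, per the labels, the green over red ratio multiplied by a factor and reduced by an offset for each array. The factors are 1 for total, 0.14 for H2A.Z total, 0.82 for AA, 0.097 for AZ and 0.036 for ZZ, and the offsets 0.512, 0.151, 0.344, 0.079 and 0.074. These deposited score values equalled that formula within 1e-05 at all 180880 features of each array. How the factors and offsets were chosen is not given in the sources used here.

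The measure here is log2 of green over red processed signal, with the median of each array set to 0, as is usual for ChIP arrays, where loess would take signal for a dye trend. A level of 0 is therefore the median probe position of that array, and a difference between 2 fractions is relative to these medians, not a difference in amount. Spots flagged as outliers and control spots were left out. Probes had to be well above background in the genomic DNA channel on all 5 arrays, which kept 176160 of 177440 genomic features. Between 99.2% and 99.4% of genomic features were well above background in the fraction channel, and 0 were saturated. The median genomic DNA intensity ran from 1859 (AA) to 2558 (ZZ). The number of arrays limits the precision.

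The arrays lay on 2 slides. The total, AA and AZ arrays shared slide 1, and the H2A.Z total and ZZ arrays shared slide 2. Slide and fraction can therefore not be told apart where ZZ or H2A.Z total is set against AZ, AA or total.

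Each of 78149 probe positions was spotted for both strands and the spots were averaged. Agreement between the strands gives a rough technical error within an array. For the mean over a +1 nucleosome, the SD of the difference between strands across genes was 0.13 for total, 0.17 for H2A.Z total, 0.12 for AA, 0.14 for AZ, 0.19 for ZZ and 0.08 for ZZ minus AZ, on the log2 scale. This covers differences between spots of the same array only. ZZ minus AZ had a smaller SD than AZ or ZZ alone. Part of the strand difference is therefore shared between arrays and is not independent error of the spots.

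The array files give probe sequences and running numbers but no coordinates or gene names, and no genome sequence was used. Overlapping probes were joined into 452 stretches of sequence, 814.34 kb in all. Whole open reading frames in them were matched to the RefSeq gene table of assembly R64 by their exact length, strand and spacing. In all, 183 stretches holding 86.4% of the joined sequence were placed. Of these, 48 were placed by 2 or more genes. Another 70 were placed by a reading frame cut by the edge of the stretch, whose length was not matched. The rest were placed by a single gene near the place predicted from probe numbers. None of the decoy stretches, the same sequences read backwards, was placed. A decoy could be placed by a single gene only if another decoy matched 2 or more genes. As none did, that outcome was fixed, and the decoys do not measure how often a real frame got a wrong name. The names thus rest on a fingerprint of lengths and on places predicted from probe numbers, not on an alignment. In all, 332 protein-coding genes on 9 chromosomes had their start codon in the placed sequence, 219 of them with the whole reading frame. Another 20 genes expected there were left out, 12 without a start codon at the place and 8 with an interrupted frame. Chromosomes III (130 genes) and VI (95 genes) hold most of them. The array design uses an older build, so no coordinates are printed, and positions are given from the start codon.

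Nucleosomes were placed on the total array alone. Values were interpolated on a 10 bp grid and smoothed over 5 grid points. The nucleosome-depleted region (NDR) was the lowest point from 400 bp upstream to 50 bp downstream of the start codon. The first maximum downstream is called +1 and the first upstream -1. All arrays were then read as the mean over probes within 70 bp of these centres, within 30 bp for the NDR, and from 500 to 1000 bp inside the gene, ending 100 bp before its stop, for the gene body. At least 2 probe positions were needed per window and 5 per gene body. Of the 332 genes, 27 were left out for thin probe coverage and 20 because the minimum lay at the edge of the search. That left 285 with an NDR, 278 with a +1, 275 with a -1 and 220 with a gene body. The steps were tested on simulated data. Each simulation planted 213 genes on the real probe positions, and 190 of them got a +1 call. With a nucleosome peak of 0.9 and linkers of -1.0, close to the mean real profile, 96.3% of the called +1 centres came back within 30 bp. With a peak of 0.3 the share was 84.7%, and 74.2% without linkers. Genes without a call are not in these shares, and no nucleosomes beyond -1 and +1 were planted. All simulated heights and depths were set after the real medians and mean profile had been seen, so the simulation checks the calling of positions and not the levels.

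SDs in the report are over genes, or over probe positions where 1 gene is named, and are not errors between replicates. Shares of genes carry 95% Wilson intervals, which cover counting error only. A gene list of at least 3 measured genes was set against 10000 random lists of equal size, each member drawn from the 39 genes nearest to it in total level at +1, and its median given as a percentile among them. Genes were named by a rule of size, fixed with the 15 gene lists before the data were examined. Among genes with a symbol it takes the 10 highest and 10 lowest by H2A.Z total at +1, the 10 highest and 10 lowest by ZZ minus AZ at +1, the 2 highest and 2 lowest of each list by H2A.Z total at +1 (fewer in lists of under 4), and every locus altered in the strain. Centromeres were found by their conserved sequence elements. Silent mating loci, tRNA genes, origins, rDNA and mitochondrial DNA are not analysed here.

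The alternatives tried were normexp background correction with an offset of 50, loess within arrays, the ratio recovered from the deposited values, no filter or a filter on both channels, correction for probe GC content, a window of 100 bp, fixed windows from the start codon, tandem genes only, no genes within 30 kb of a chromosome end, at least 3 probes, the median of probes, unmatched random lists, smoothing over 11 grid points, a size threshold of 0.5, and other uses of the labels' factors and offsets. Software was R 4.3.3 with limma 3.58.1 and data.table (version 1.17.8), and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.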

Results

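The series maps where nucleosomes carrying 0, 1 or 2 copies of the histone variant H2A.Z lie in the genome of Saccharomyces cerevisiae. The variant replaces H2A next to gene promoters, where the SWR1 remodelling complex installs it. Total nucleosomes, the whole H2A.Z-containing fraction and the AA, AZ and ZZ fractions of G1-arrested cells were each hybridised to 1 tiling array against genomic DNA. Median intensities of the fraction channel were 2121 for total, 2157 for H2A.Z total, 2163 for AA, 2320 for AZ and 1718 for ZZ. There were no replicate arrays, so every difference below compares these 5 arrays.

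The first question is what each fraction looks like around the start of a gene. Promoters held a nucleosome-depleted region flanked by nucleosomes in which H2A.Z stood far above its array median. The NDR centre lay at a median of -160 bp from the start codon (SD over genes 97.6 bp), the +1 centre at -20 bp (SD 93.4) and the -1 centre at -290 bp (SD 109). The -1 and +1 centres were a median of 260 bp apart. On the total array the NDR stood at -2.25 (SD 0.81, n = 285 genes), +1 at 0.34 (SD 0.63, n = 278), -1 at 0.33 (SD 0.75, n = 275) and the gene body at 0.09 (SD 0.38, n = 220), all as log2 of fraction over genomic DNA. The NDR, +1 and -1 are extremes of this same array, so these total levels are partly fixed by the calling. The mean total profile from the start codon fell only to -1.16. With a window of 100 bp, total was -0.13 at both +1 and -1, and with fixed windows it was -0.01 at -1. H2A.Z total was -0.92 in the NDR (SD 0.99), 2.44 at +1 (SD 1.19), 2.07 at -1 (SD 1.29) and -0.04 in the gene body (SD 0.73).

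The 3 nucleosome types parted at promoters. AA was at -2.6 in the NDR (SD 0.86), -0.47 at +1 (SD 0.63), -0.38 at -1 (SD 0.80) and 0.17 in the gene body (SD 0.51). AZ was at -1.51 (SD 0.97), 1.57 (SD 1.03), 1.36 (SD 1.1) and 0.02 (SD 0.70) in the same order. ZZ was at 0.19 (SD 1.05), 3.92 (SD 1.5), 3.40 (SD 1.61) and -0.41 (SD 0.99). The ZZ median in the NDR thus lay slightly above that array's own median, while the 4 other arrays were below theirs there. With normexp the ZZ median in the NDR was -0.06, so its sign depends on the background correction. The median ratio of the ZZ array was 0.77, while the labels' offset puts zero at a ratio of 2.06. A level slightly above the array median is thus below zero on the labels' scale, and does not by itself show ZZ nucleosomes in the NDR.

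**Figure D1:**
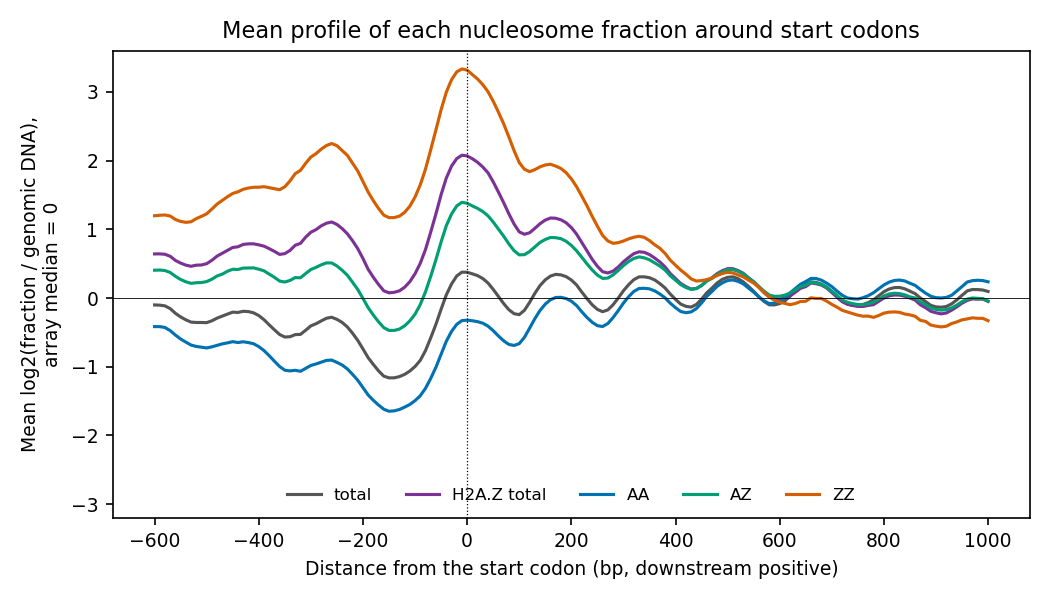
Mean log2 ratio of fraction over genomic DNA (vertical axis, array median at 0) against distance from the start codon in bp (horizontal axis), 1 line per array, averaged over the 169 to 329 genes with data at each distance. At 10 bp upstream of the start codon the ZZ line stands at 3.34, H2A.Z total at 2.08, AZ at 1.39, total at 0.38 and AA at -0.33, and the lines come together inside the gene.

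The second comparison asks how far H2A.Z is confined to the +1 nucleosome rather than spread over the gene. H2A.Z total was higher at +1 than in the body of the same gene by a median of 2.44 (SD 1.07, n = 188 genes). In 91.0% of the 188 genes (95% interval 86.0 to 94.3%) the difference was over 1 on the log2 scale. That share was 82.4% with normexp and with a window of 100 bp, 81.3% with fixed windows and 68.1% with loess, which also lowered the median to 1.32, and that of ZZ to 1.49. Unaltered, the difference was 1.5 for AZ (SD 0.93), 4.20 for ZZ (SD 1.49), 0.29 for total (SD 0.58) and -0.70 for AA (SD 0.70). The total difference was -0.21 with a window of 100 bp. These are differences within an array and do not depend on its centring.

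Genes with the highest H2A.Z total at +1 were IOC3, a subunit of an Isw1 remodelling complex, at 3.54 (SD over probes 0.50) and PTC6, a mitochondrial protein phosphatase, at 3.49 (SD 0.58). Next came CAK1, the kinase that activates cyclin-dependent kinases, at 3.43, the mitochondrial ribosomal protein gene IMG2 at 3.41, the thioredoxin gene TRX3 at 3.35 and LSB5 at 3.33. SEN34, a subunit of the tRNA splicing endonuclease, was also at 3.33. The mRNA decay factor PAT1, the bud site gene BUD3 and the septin gene CDC10 each stood at 3.31. Their total levels at +1 lay between 0.45 (SEN34) and 1.12 (CAK1). A divergent upstream neighbour was found for 6 of the 10, and for 120 of the 271 genes with both nucleosomes. PTC6 and PAT1 share both nucleosomes, with +1 and -1 exchanged, so they are not separate cases. With loess, which also takes out signal, the median over all genes was 1.24. PTC6 (0.44), BUD3 (0.72), LSB5 (0.79), PAT1 (0.86) and IMG2 (0.89) then fell below it, while IOC3, CAK1, TRX3, SEN34 and CDC10 stayed above.

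At the other end, 3 genes that mating pheromone induces were among the 10 lowest: FUS1, needed for cell fusion, at -1.93 (SD over probes 0.15), the mating adhesin gene FIG2 at -1.22 (SD 0.29) and the karyogamy transcription factor KAR4 at -1.13 (SD 0.20). The other 7 were VAC17 (-2.40), the kinase subunit gene CTK2 (-2.33), MIN10 (-2.05), the lysine biosynthesis gene LYS4 (-2.00), RPL22B (-1.69), the beta-tubulin gene TUB2 (-1.11) and MIM1 (-0.99). For 8 of the 10 the total array was under -1 at the called +1, so the call lies in depleted chromatin. With windows at fixed distances from the start codon, 6 of the 10 turned positive, for example TUB2 (2.83) and CTK2 (2.86), whereas MIN10, FUS1, FIG2 and KAR4 stayed negative.

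**Figure D2:**
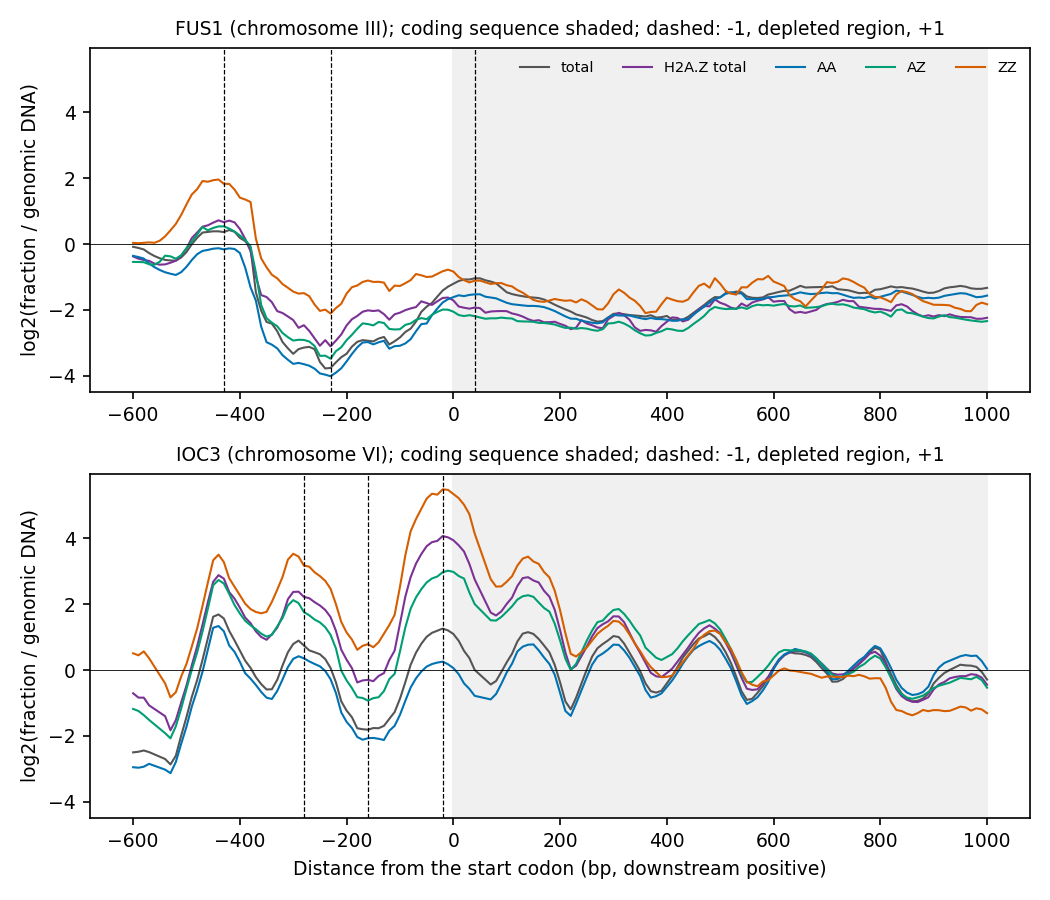
Log2 ratio of fraction over genomic DNA (vertical axis) around the start codons of FUS1 (upper panel) and IOC3 (lower panel), in bp from the start codon, 1 line per array. Dashed lines mark the called -1, NDR and +1, and shading the coding sequence. At the FUS1 +1 the ZZ line averages -1.09, and at the IOC3 +1 it averages 4.96.

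The third comparison sets the 2 nucleosomes flanking the NDR against each other. In H2A.Z total, +1 was above -1 by a median of 0.29 (SD 1.27, n = 271 genes), in 62.7% of genes (95% interval 56.8 to 68.3%). For AZ the median was 0.20 (SD 1.1), with +1 higher in 59.8% of genes (53.8 to 65.4%). For ZZ it was 0.37 (SD 1.56), with +1 higher in 61.3% (55.3 to 66.9%). Total differed by 0.05 (SD 0.87) and AA by -0.07 (SD 0.92).

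In the 122 tandem genes, whose upstream neighbour runs in the same direction, H2A.Z total was higher at +1 by 0.49 (SD 1.04), and +1 was the higher one in 75.4% (67.1 to 82.2%). AZ was higher by 0.36 (SD 0.87), in 71.3% of genes (62.7 to 78.6%), and ZZ by 0.94 (SD 1.39), in 73.0% (64.5 to 80.0%). In the 120 genes with a divergent neighbour the medians were -0.03 for H2A.Z total (SD 1.31), -0.05 for AZ (SD 1.18) and -0.03 for ZZ (SD 1.54). There +1 was higher in 48.3%, 47.5% and 48.3% of genes. Of these 120 genes, 70 share both nucleosomes with a measured neighbour within 70 bp, with +1 and -1 exchanged, and 34 of them have exactly exchanged values. Such pairs cancel, so a balance near 0 and 50% is largely fixed by construction, is no contrast to the tandem genes, and also draws the values over all 271 genes, with their intervals, towards balance. The medians in both sets are smaller than the spread over genes. With fixed windows, the divergent genes had +1 higher in 58.1% for H2A.Z total and 60.5% for ZZ. Loess, which also takes out signal, left +1 higher in 48.4% of tandem genes for H2A.Z total, with a median of -0.10.

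The fourth comparison is between the nucleosome types at the same place. At +1, ZZ exceeded AZ by a median of 2.25 (SD 0.66, n = 278 genes) and AA by 4.38 (SD 1.47), and AZ exceeded AA by 2.02 (SD 0.87). At -1 the same differences were 1.96 (SD 0.77), 3.65 (SD 1.57) and 1.73 (SD 0.90). In gene bodies the order on this centred scale turned: ZZ minus AZ was -0.33 (SD 0.61), ZZ minus AA -0.60 (SD 1.06) and AZ minus AA -0.18 (SD 0.56). Each array is centred on its own median, so these orders are relative to the medians and not orders of amount. On the labels' scale the AA median was above that of ZZ both at +1 (0.448 against 0.388) and in gene bodies (0.861 against -0.052). AZ and AA shared a slide, while ZZ was on the other one, so only AZ against AA is free of the slide.

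The balance of homotypic and heterotypic H2A.Z nucleosomes was then compared gene by gene, as ZZ minus AZ at +1. AZ and ZZ levels went together across genes, with a correlation of 0.931 over 278 genes, which are not independent replicates. The slope of ZZ on AZ was 1.36 (standard error over genes 0.03), so ZZ minus AZ was larger where AZ was high. Relative to its median, 27 genes were lower by over 1 on the log2 scale and 1 was higher: YCR051W, at 3.32, which has no symbol and is named here after its value was seen.

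The 10 highest with a symbol were SOL2 at 3.15, PTC6 at 3.03, RBP95 at 2.94, TUP1, a general corepressor, at 2.93, and the proteasome subunit gene PRE3, CDC50, ERS1 and IMG2, each at 2.92. MDM38 followed at 2.87 and the cytochrome oxidase assembly gene COX16 at 2.85. All 10 lay within 1 of the median. With loess SOL2, PTC6, IMG2, ERS1 and MDM38 turned negative, from -0.14 to -0.31. The lowest were the magnesium transporter gene ALR2 at -0.60, the acetate transporter gene ADY2 at -0.02, ULI1 at 0.39, the meiotic recombination gene MSH4 at 0.64, RRT5 at 0.86 and FUS1 at 1.09. The sporulation septin gene SPR28 and the DNA polymerase gene POL4 were each at 1.17, DCV1 at 1.19 and the stress-induced HSP30 at 1.23. At the called +1, ALR2 and ADY2 had total at 0.27 and 0.75, AA at 0.54 and 0.71, and H2A.Z total at 0.07 and 0.03. Their NDRs were shallow (total -0.58 and -0.24), so these +1 calls are uncertain, and H2A.Z total changed sign under some alternatives (ALR2 -0.39 with loess, ADY2 -0.60 with normexp). The ZZ minus AZ of a gene had a technical SD between strand spots of 0.08. Loess lowered the median of ZZ minus AZ at +1 to 0.29 and the slope to 0.887.

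**Figure D3:**
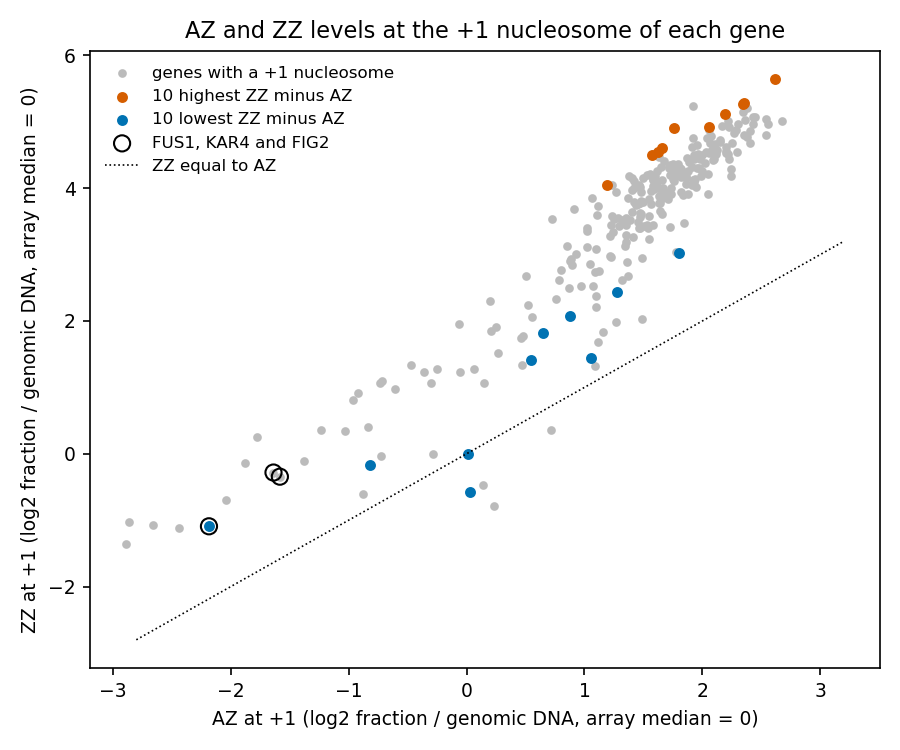
AZ (horizontal axis) against ZZ (vertical axis) at the +1 nucleosome, both as log2 of fraction over genomic DNA with the array median at 0, 1 point per gene (278 genes). Orange and blue points are the 10 genes with a symbol and the highest or lowest ZZ minus AZ, open circles FUS1, KAR4 and FIG2, and the dotted line marks equal values. Most points lie above the line and rise with a slope of 1.36.

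On the common scale that the labels' factors and offsets define, the 3 types were added. How the factors were chosen is not given, so sums close to total or H2A.Z total are no test of that scale. The AA, AZ and ZZ medians at +1 were 0.448 (SD 0.305), 0.256 (SD 0.147) and 0.388 (SD 0.289), n = 278 genes. Their sum per gene had a median of 1.13 (SD 0.538) against 1.05 for total (SD 0.474), a difference of 0.069 (SD 0.242). AZ plus ZZ was 0.647 (SD 0.427) against 0.671 for H2A.Z total (SD 0.403), a difference of -0.018 (SD 0.120). Across genes at +1 the sum of the 3 types correlated with total at 0.893, and AZ plus ZZ with H2A.Z total at 0.960. Over 77636 probe positions the correlations were 0.954 and 0.982.

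As median shares of the sum, AA made up 39.2% at +1 (SD 25.5), AZ 23.2% (SD 8.14) and ZZ 36.3% (SD 18.3), over the 263 genes with a sum above 0.1. At -1 the shares were 49.9% (SD 27.1), 22.1% (SD 8.46) and 25.8% (SD 20.2), over 257 genes. In gene bodies AA was at 102% (SD 13.3), AZ at 3.53% (SD 6.46) and ZZ at -5.56% (SD 7.21), over 215 genes. Shares below 0 and above 100% arise because the offset is larger than the signal there. The median of total was 1.05 at -1 (SD 0.544) and 0.754 in gene bodies (SD 0.249), and that of the summed types 1.05 (SD 0.583) and 0.872 (SD 0.259). At -1, AA stood at 0.494 (SD 0.381), AZ at 0.212 (SD 0.153), ZZ at 0.252 (SD 0.292), AZ plus ZZ at 0.469 (SD 0.431) and H2A.Z total at 0.516 (SD 0.417). In gene bodies these were 0.861 (SD 0.237), 0.031 (SD 0.057), -0.052 (SD 0.055), -0.020 (SD 0.105) and -0.009 (SD 0.103). All of these rest on the factors in the labels. A least-squares fit of scaled total on scaled AA, AZ and ZZ gave coefficients of 0.854, 2.41 and 0.127, so other relative factors would change the shares.

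**Figure D4:**
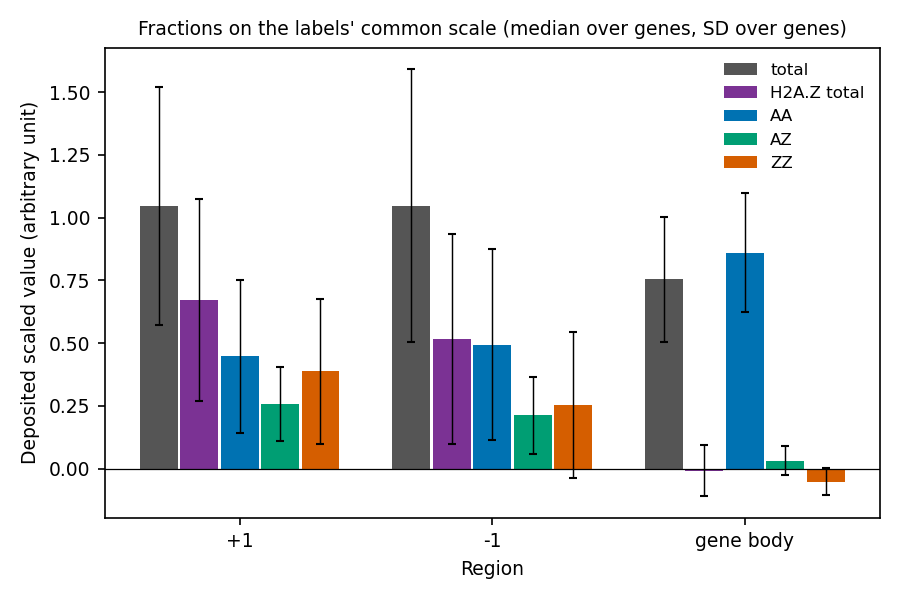
Deposited scaled values (vertical axis, arbitrary unit) at +1, -1 and in gene bodies, as median over genes with bars of 1 SD over genes, for the 5 arrays. At +1 AA, AZ and ZZ reach 0.448, 0.256 and 0.388, and in gene bodies AA reaches 0.861 with AZ and ZZ near 0.

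Gene groups were compared at +1 through lists fixed in advance, of which 11 had a named gene on the array. The 3 measured pheromone-induced genes had a median H2A.Z total of -1.22, at the 0.24 percentile of random lists drawn from the genes nearest in total. Their AA median was -1.63 (percentile 1.15), AZ -1.64 (percentile 0.285) and ZZ -0.34 (percentile 1.40). The AA percentile passed 2.5 with normexp (29.1), with a window of 100 bp (3.78), with fixed windows (4.15) and with the median of probes (2.71). The ZZ percentile did so with loess (8.62) and with the median of probes (3.00). H2A.Z total and AZ stayed below 2.5 in each alternative. The draw did not match these genes in total: the pools had a median total of -0.26 for FUS1 (itself at -1.19), -0.42 for FIG2 (-1.88) and -0.20 for KAR4 (-0.51). The percentiles therefore do not separate low H2A.Z from low total.

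The 4 other lists of 3 or 4 measured genes lay within the central 95% of random lists. With loess the ribosome biogenesis genes left that range in AZ, at the 99.7 percentile. The 4 ribosome biogenesis genes had a median H2A.Z total of 2.60 (percentile 85.2), AA -0.76 (13.3), AZ 1.69 (86.1) and ZZ 3.96 (66.8). KRR1 was at 3.21, LOC1 at 2.71, SPB4 at 2.49 and UTP20 at 2.45. The 3 proteasome genes were at 2.35 (percentile 33.1), AA -0.80 (4.32), AZ 1.65 (59.9) and ZZ 4.30 (87.4), with PRE3 at 2.64 and RPN12 at 2.26 in H2A.Z total. The 3 G2/M genes were at 2.79 (percentile 66.5), AA -0.53 (10), AZ 1.73 (50.6) and ZZ 3.92 (35.2), from BUD3 (3.31) to the polo kinase gene CDC5 (2.25). The 3 amino acid biosynthesis genes were at 2.49 (percentile 27.6) in H2A.Z total and -0.07 (65.8) in AA, whose median was -1.17 with normexp. Their AZ was 1.51 (13.0) and their ZZ 3.43 (13.9). In H2A.Z total they ran from HIS2 (3.11) to HIS4 (2.05). Single members of these lists moved under some alternatives. For example, H2A.Z total fell with normexp to 0.83 at CDC5 and 0.61 at HIS4. With fixed windows it fell to 1.01 at HIS4 and 1.28 at PRE3.

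Lists with 1 or 2 measured genes have only single values in H2A.Z total at +1. The G1/S genes SMC1 (cohesin) and RFA1 (replication protein A) were at 2.98 and 2.26, and the meiosis and sporulation genes SPR28 and MSH4 at 1.61 and -0.57 (MSH4 0.90 with fixed windows). The glycolytic gene PGK1 was at -0.29 (0.16 with loess, -1.71 with normexp), HSP30 at 2.34 (1.25 with normexp, 1.30 with fixed windows), the respiratory chain gene RIP1 at 1.93 and the ribosomal protein gene RPL22B at -1.69.

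Among special regions, 4 centromeres (chromosomes I, III, VI and X) were low on all 5 arrays. Over 70 bp on either side of their middle, total stood at -2.36 (SD over centromeres 0.26), H2A.Z total at -1.42 (SD 0.28), AA at -2.30 (SD 0.41), AZ at -1.61 (SD 0.17) and ZZ at -0.49 (SD 0.20). These elements are 86.2 to 88.2% A and T, and only 6 to 9 of their 11 to 14 probe positions passed the filter. Without it the ZZ value was 0.48. The 11 snoRNA genes had total at -0.13 (SD 0.40), H2A.Z total at -0.62 (SD 0.89), AA at -0.08 (SD 0.35), AZ at -0.78 (SD 0.77) and ZZ at -0.45 (SD 1.17). With loess their total, AA and ZZ turned positive, at 0.17, 0.20 and 0.04.

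Only on chromosome III did the named genes come close to both ends of the gene table. Distance to an end was estimated from its outermost probes by probe number. Its 12 measured genes within 30 kb of an end, so defined, had H2A.Z total of 2.62 at +1 (SD 1.96), AA -0.38 (SD 0.98), AZ 1.63 (SD 1.70) and ZZ 4.01 (SD 2.43). Its 98 other genes were at 2.55 (SD 1.08), -0.49 (SD 0.51), 1.66 (SD 0.91) and 4.06 (SD 1.41). The medians differed by less than the spread over genes, and that spread was wider near the ends.

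The strain's deletions could be checked, in both channels, at 1 locus only. LEU2, which the BY4741 background lacks, was the only one of the altered loci found among the named genes. Its 100 probe positions had median intensities of 1.70 to 4.02 in the genomic DNA channel and 1.72 to 8.67 in the fraction channel, against array medians of 1864 to 2574 and 1750 to 2363. At NFS1, its neighbour, 145 positions were at 2510 to 3608 and 1747 to 3645.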

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

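No paired analysis was possible because each fraction has 1 array. Leaving out the dimmest probes in both channels, leaving out genes near chromosome ends, smoothing over 11 grid points, unmatched random lists and setting negative scaled values to 0 moved no main result by more than the spread over genes or, for shares, outside the 95% interval. Asking for at least 3 probes moved nothing either. It had no room to act at +1, where each window held at least 9 positions, or in gene bodies, which already needed 5. The ratio recovered from the deposited values and the scaled values made from the scanner files equalled the values used by construction, apart from rounding in the deposited file, and test nothing. Over all alternatives, 1436 values of main results stayed within these limits, 82 moved and 1 that exceeded its spread turned its sign. Of named genes' values 859 stayed, 99 moved and 22 that exceeded their spread turned. Those that stayed include 107 main and 98 named-gene values with at least 3 probes. They also include 117 main and 98 named-gene values of the recovered ratio and 34 main values scaled from the scanner files. With values smaller than their spread included, 40 values of main results and 30 of named genes had the other sign. Of these, H2A.Z total at +1 moved to 0.16 at PGK1 and -0.39 at ALR2 with loess, and to -0.60 with normexp and -0.42 with fixed windows at ADY2. One alternative kept only genes whose total at +1 was above a log2 level of -1, and was chosen after seeing the data. It left 268 genes and moved only the slope of ZZ on AZ, to 1.51. Where background was corrected by normexp instead, the centromeres, the share of genes over the gene body, the slope, the pheromone AA percentile, the amino acid biosynthesis AA median and DCV1 gave the values below.

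Loess, which fits the ratio on brightness and so by its construction removes enrichment along with dye trends, lowered H2A.Z total at +1 to 1.24, ZZ at +1 to 1.33 and at -1 to 1.40, H2A.Z total at +1 minus gene body to 1.32 (over 1 in 68.1% of genes) and ZZ at +1 minus gene body to 1.49. ZZ minus AZ became 0.29 at +1 and 0.41 at -1, and ZZ minus AA 1.81 at both. The slope was 0.887 and the correlation of AZ and ZZ 0.738, with 41 genes above and 1 below the median by over 1. Genes with +1 above -1 were 48.3%, 49.1% and 45.4% for H2A.Z total, AZ and ZZ, and 48.4%, 49.2% and 43.4% in tandem genes, and the medians of +1 minus -1 turned to -0.10, -0.02 and -0.16, and to -0.10, -0.01 and -0.30 in tandem genes. On chromosome III, H2A.Z total of genes away from the ends was 1.21, and ZZ was 1.45 near the ends and 1.27 elsewhere. Centromeres were at -1.60 (total), -1.06 (H2A.Z total), -1.16 (AA) and -1.18 (AZ). List medians of ZZ were 2.01 (G2/M), 1.86 (amino acid biosynthesis), 1.21 (proteasome) and 1.97 (ribosome biogenesis), and of H2A.Z total 1.07 (proteasome); the ribosome biogenesis percentile in AZ was 99.7 and the pheromone percentile in ZZ 8.62. ZZ minus AZ turned negative at SOL2 (-0.21), PTC6 (-0.31), IMG2 (-0.20), ERS1 (-0.14), MDM38 (-0.15), PAT1 (-0.20), BUD3 (-0.40), LSB5 (-0.36), SEN34 (-0.17), CAK1 (-0.32), IOC3 (-0.32), KRR1 (-0.16), SMC1 (-0.064) and RPN12 (-0.27).

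For the other alternatives the cause was not tested unless named. With fixed windows, H2A.Z total at +1 turned positive at VAC17 (1.87), LYS4 (1.33), MSH4 (0.90), RPL22B (1.82), TUB2 (2.83), CTK2 (2.86) and MIM1 (0.82). Genes with +1 over 1 above the gene body were 81.3%, +1 above -1 was found in 69.1% (H2A.Z total) and 70.9% (ZZ) of genes and in 58.1% and 60.5% of divergent ones, 0 genes were above the median of ZZ minus AZ by over 1, the slope was 1.40 and the pheromone AA percentile 4.15. A window of 100 bp gave 82.4% over the gene body, 0 genes above and an AA percentile of 3.78. The median of probes gave pheromone percentiles of 2.71 (AA) and 3.00 (ZZ). Normexp gave 82.4% over the gene body, a slope of 1.30, a pheromone AA percentile of 29.1, an AA median of -1.17 for amino acid biosynthesis, H2A.Z total of -0.11 at DCV1, and centromeres at -4.97 (total), -3.71 (H2A.Z total), -5.05 (AA), -4.39 (AZ) and -2.62 (ZZ). Without the filter, centromeres were at -1.37, -0.56, -1.33, -0.74 and 0.48 in that order. Corrected for GC, they were at -1.96 (total), -1.56 (AA), -1.33 (AZ) and -0.73 (ZZ). Tandem genes alone had +1 above -1 in 75.4%, 71.3% and 73.0% for H2A.Z total, AZ and ZZ, 0 genes above and 15 below the median by over 1, and a slope of 1.54. A threshold of 0.5 gave 24 above and 64 below. Factors without offsets, which raise every value by construction, gave at +1 1.56 (total) and 0.792 (AA), and in gene bodies 1.27 (total), 0.142 (H2A.Z total), 1.20 (AA), 0.110 (AZ), 0.022 (ZZ), 1.37 (sum of 3 types) and 0.133 (AZ plus ZZ).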

Other observations

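H2A.Z stepped down nucleosome by nucleosome into the gene. Maxima of the mean total profile followed +1 at 170, 340, 500 and 670 bp. H2A.Z total was 2.44 at +1 (SD over genes 1.19), 1.34 at +2 (SD 0.78), 0.75 at +3 (SD 0.74), 0.33 at +4 (SD 0.70) and 0.11 at +5 (SD 0.65). ZZ spanned a wider range, from 3.92 at +1 through 2.26 and 0.85 to 0.23 and -0.30, while AZ went from 1.57 through 1.01, 0.70 and 0.37 to 0.16. AA ran the other way, from -0.47 through -0.06, 0.12 and 0.19 to 0.24, and total stayed between 0.34 and 0.16. Between 278 genes at +1 and 192 at +5 entered these medians. At +3, ZZ (0.85) and AZ (0.70) stood closer together than at +1.

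The genes that alpha factor induces were also depleted along their bodies. On the total array the body of FIG2 was at -2.27, of STE2, the alpha-factor receptor, at -1.82, of FUS1 at -1.41 and of KAR4 at -0.70. They ranked 2, 3, 4 and 6 from the lowest of 220 genes. In H2A.Z total they were at -2.34, -2.28, -1.93 and -1.53. STE2 has no +1 call and is named here after its value was seen.

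The tests in this and the next 2 paragraphs were chosen after the patterns had been seen, with the outcomes that would speak for or against each cause written down before the tests were run, except for the comparison of FUS1, FIG2 and KAR4 with the genes nearest in total, which was chosen after the differences had been seen. The first pattern is the low H2A.Z at +1 of FUS1, FIG2 and KAR4. H2A.Z total minus total was -0.74 at FUS1, -0.62 at KAR4 and 0.66 at FIG2, a median of -0.62, at the 0.364 percentile of the other genes, whose median was 2.10. That percentile had been set to exclude a loss of nucleosomes of all types, but the median over the 3 genes hides FIG2, and most of the other genes are not depleted. The 10 other genes nearest in total had a median of 1.18 for FUS1 (SD 0.99, lowest -0.27), 1.63 for KAR4 (SD 1.14, lowest -0.22) and 0.89 for FIG2 (SD 0.52, lowest -0.27). FUS1 and KAR4 lie below all of theirs, by slightly less than 2 SD from the median, and FIG2 lies among its own. The genes nearest to FIG2 include VAC17, CTK2, LYS4, RPL22B, TUB2 and MIM1, whose H2A.Z total turned positive with fixed windows. MIM1 is also the lowest for FUS1. Their called +1 may lie inside the depleted region, so they cannot show what loss of nucleosomes does, and the place of FIG2 among them decides nothing. A misplaced +1 would leave a high H2A.Z peak nearby, but the highest H2A.Z total within 300 bp of the start codon had a median of -1.18, with 0% of the other genes lower. Loss of nucleosomes of all types thus stays open for the 3 genes. Only 8 other genes had total at +1 at or under -1, so FUS1 and FIG2 have few close matches. KAR4, with total at -0.51, has close ones (-0.67 to -0.37), but it stays within 2 SD of their median. The series has no cells without pheromone, so an effect of pheromone was not tested.

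The second pattern is that AZ was scarcer at +1 than independent pairing of H2A and H2A.Z dimers would make it. On the labels' scale, H2A.Z made up a median of 50.0% of dimers at +1 over 243 genes with all 3 types above 0. AZ was 23.6% where independent pairing gives 47.8%, a median ratio of 0.505 (SD 0.105), under 1 in 243 of 243 genes. Mixing of neighbouring nucleosomes within the window would bring the ratio near 1 close to the centre, but within 20 bp it was 0.482. Wrong factors in the labels cannot be told apart from true scarcity. For too low an AZ factor alone, AZ would have to be 3.10 times larger. A fit of H2A.Z total on AZ and ZZ gave AZ a coefficient of 1.15 (jackknife error 0.02). By the outcome written beforehand this speaks against too low an AZ factor. That fit, however, uses only the fraction from which AZ was taken. A fit of total on AA, AZ and ZZ gave 0.854, 2.41 and 0.127. Here too AZ (error 0.09) lay below 3.10. With these 3 coefficients the ratio was 1.33, a calculation added after the first fit had been seen, but ZZ was cut as well. AZ and ZZ correlated at 0.846 over positions, which limits how well a fit can divide signal between them, and the 2 fits disagree. Cells that differ in H2A.Z, and AZ lost in the immunoprecipitation, stay open and were not tested.

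The third pattern is the slope of 1.36 of ZZ on AZ at +1. The genomic DNA channels of the AZ and ZZ arrays, on different slides, differed by only 0.0112 per unit of AZ (standard error 0.003), against the 0.36 needed. With the labels' offsets subtracted, the slope over the 229 genes with both scaled values above 0.05 was 1.29 (standard error 0.05). This was set to exclude a constant background, but it does not, because the labels do not say that the offsets are the background, and the ZZ offset, at a ratio of 2.06 against 0.814 for AZ, itself changes the slope. Loess took the slope to 0.887 and ZZ minus AZ at +1 from 2.25 to 0.29, but it removes enrichment along with any trend on brightness. What stays open is a constant background, a brightness or dye trend, for which there is no dye swap, a difference between the slides or antibodies in the fraction channel, which the design confounds with the fraction, and a true excess of ZZ where H2A.Z is high, which was not tested.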
